A study of Plasmodium falciparum with 24 samples.

How the data were processed

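The labels describe 24 arrays with 2 channels each. The Cy5 channel held RNA of P. falciparum 3D7 from a control or doxycycline arm at 1 of 12 times, and the Cy3 channel held a common 3D7 total RNA reference pool, per the labels. The deposited values are log2 ratios, 1 per probe and array, for 8832 probes. The base was read from the values, since a recurring cap of 16.6096 equals log2 of 100000. The direction, sample over reference pool, was taken from the dyes in the labels. It was checked on blank values, of which 79.1% among 646 fell where the neighbouring times of the same probe lay below its mean, as a vanishing sample signal would give. How the authors corrected background, normalized and filtered the values is not given in the sources used here, and the array medians ranged from -0.86 to 0.35. Some arrays of distant stages opposed each other, the lowest correlation being -0.47 between the doxycycline arrays of 10 h and 25 h. The labels state the dyes and stages of the cycle can oppose, so the direction was kept. Values at the cap were treated as missing.

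Probes named as empty spots (680) and probes whose names start with Y (84), Z (76) or OTHER (6) were left out, which left 7986 parasite probes in 7979 features. A feature is the mean of its probes where probes share a name, and a probe ID otherwise. Of the parasite probes, 90.7% have no gene name. None of the 639 locus tags among the probe names was found in the reference gene table of 5615 genes. The 23 gene lists fixed before the data were examined, with 110 members given by identifier, matched 0 probe names, so organelle pathways, stage programmes, surface families, stress genes and gametocyte markers were not analysed here, nor was a mitochondrial list. The apicoplast genome list (54 features, 53 tested), nuclear tRNAs and rRNA were instead taken from the probe names before any test. The rRNA list includes 9 probes whose names say only rRNA, and the nuclear tRNA list 5 features named unmapped.

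Each array was centred on its median over features. Features needed at least 4 complete time pairs in the early period (0 to 25 h) and 4 in the late period (30 to 55 h), which left 7549. The fit used limma 3.58.1 in R 4.3.3, with time as a 12-level block and separate doxycycline effects in each period, Benjamini-Hochberg adjustment over all features and a threshold of 0.05. It was computed as the equivalent fit on time-paired differences. Data for 7549 features were simulated with a late change in 200. The late contrast recovered 68 of 100 changes of 1 on the log2 scale and 97 of 100 of 2, with 13 false calls. Late minus early recovered 40 and 85 of 100, with 7 false calls. The simulated noise was independent between features and times, so these rates need not hold for the measured features, which are correlated. List means were tested by two-sided exact sign-flip permutation over times and, for late minus early, by exact permutation of 924 splits of the period labels. Sets were tested with camera (preset correlation of 0.01, and estimated) and fry. On 200 simulated lists of 53 features with the measured correlation and no shift, sign-flip called 2.0%, camera with the preset correlation 67.5% and camera with the estimated correlation 3.5%. The noise here was symmetric and independent between times, and no control array was shared between pairs. The sign-flip rate was thus low by construction, and these rates need not hold for the measured times, which are serial.

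Stage was matched by the highest Pearson correlation across features with controls interpolated to 1 h steps. Profile correlations needed at least 8 pairs. The rule for named genes, fixed before the data were examined, takes, where fewer than 3 features pass in a direction, the 5 with the largest moderated t in that direction, said not to pass, each apicoplast genome gene, and the 2 highest and 2 lowest late values of other lists. Some of the apicoplast ribosomal protein genes are not reported by name here. Probe IDs without gene names were limited to 2 in each direction. Alternatives covered the scaling, probes, missing values, time terms, times left out, period boundaries, array weights, the prior and stage alignment. Leaving out the 30 h and 50 h or the 30 h and 45 h pairs, averaging the 45 h and 50 h pairs as 1 pair, leaving out the 30 h or 45 h pair under array weights, and leaving out a pair with the interpolated control were chosen after seeing the data. The scaling moved the median difference of all features to -0.11 as deposited, against 0.0015 after centring and 0.0082 after quantile normalization. Figures were drawn with matplotlib 3.10.9.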

Results

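Transcript levels were measured on 24 oligonucleotide arrays of Plasmodium falciparum strain 3D7, a laboratory strain of the malaria parasite grown in blood culture. The parasites of one arm were treated with doxycycline, a tetracycline antibiotic that binds bacterial-type ribosomes, and those of the other arm were not. Each arm was sampled every 5 h from 0 to 55 h, with 1 array per arm and time, so each arm had 12 arrays. The dose of doxycycline is not given in the labels. The sample on each array was labelled with Cy5 and set against a common 3D7 total RNA reference pool labelled with Cy3. The values are log2 ratios of sample over reference pool, and the number of arrays limits their precision. The times are serial samples, and the labels name no separate cultures, so a p-value here measures how steady a difference was over the times and not the spread between cultures. The control arrays of 45 h and 50 h were nearly identical, with 834 equal values and a correlation of 0.994 across parasite probes, against at most 0.922 in any other pair of arrays. The tests below use all 12 time pairs, and the main value is also given with the 45 h and 50 h pairs averaged as 1 pair.

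The first comparison asked whether treated parasites moved through the cycle at the pace of the control. Both arms passed through the same sequence of expression. The best matching control time lay within 3 h of the sampling time for every doxycycline array from 0 to 50 h, with a median absolute offset of 1 h over all 12 arrays. The correlation across features with that match was 0.94 at 0 h and 0.939 at 45 h, and it was lowest at 30 h, at 0.72. The doxycycline array of 30 h had 52.9% of its empty spots missing and an array median of -0.86, and it matched the control at 27 h. It also held 335 parasite values of exactly 0, against at most 150 in any other array. Its parasite probes were missing at 4.53%, against up to 6.84% in other arrays, with an SD of 1.14. A failed hybridisation and a difference of the parasites are both left open. The doxycycline array of 55 h matched the control at 3 h with a correlation of 0.815, against 0.703 with the control of 55 h. These are correlations across features within arrays, and features are not independent replicates. No test was made of the offsets. Those of 45 h and 50 h rest on the nearly identical control arrays of these times. Across parasite probes, the doxycycline array of 45 h correlated with them at 0.921 and 0.922, and that of 50 h at 0.843 and 0.844. These controls therefore cannot tell 45 h from 50 h.

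**Figure D1:**
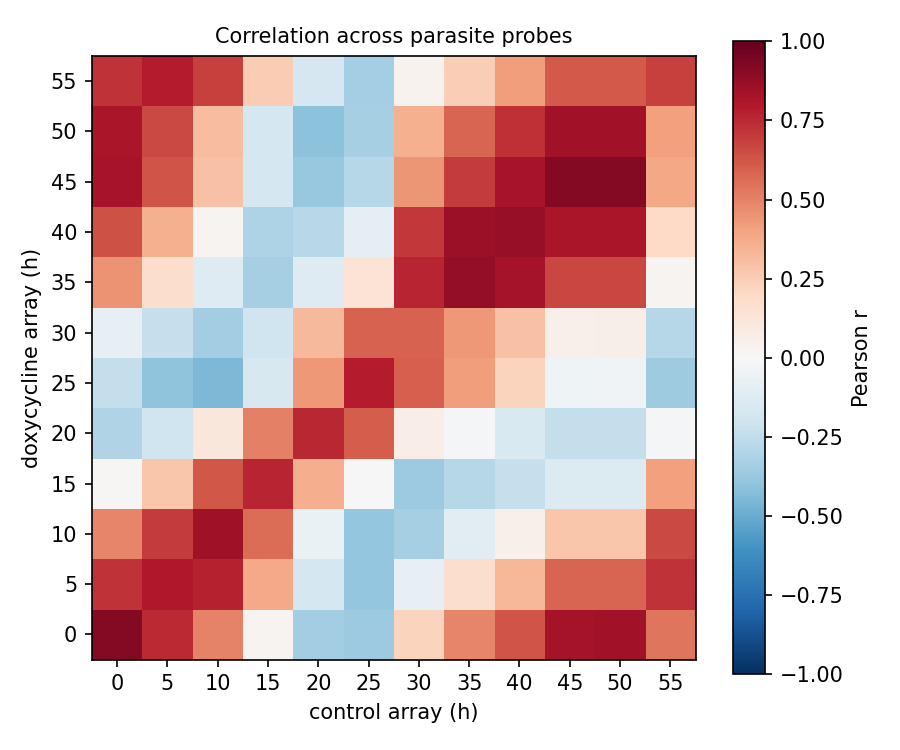
Pearson correlation across parasite probes between each doxycycline array (vertical axis, sampling time in h) and each control array (horizontal axis, sampling time in h), with colour from -1 to 1. High values follow the diagonal, and the doxycycline array of 55 h is also close to the control arrays of 0 h and 5 h.

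The order of expression over the cycle was largely kept, and less so for the apicoplast genome. The median correlation of a feature's profile between the arms was 0.763 over 7549 features, against -0.0111 for randomly paired features. The 238 empty spots with at least 10 pairs had a median of 0.43 on the values as deposited. They hold no parasite probe, so a correlation between the arms can arise without parasite signal. HRPII and HRPIII, histidine-rich proteins of the parasite, had profile correlations of 0.988 and 0.982, HRP had 0.826, and pfcrt, a transporter of the digestive vacuole linked to chloroquine resistance, had 0.907. The 53 measured features of the apicoplast genome had a median of 0.486, near the 0.43 of the empty spots. Features with a similar spread over the control times had a median of 0.81, and none of 10000 random lists of 53 such features had a median as low. This describes these arrays and is no test, since the profiles of apicoplast features are correlated.

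The second comparison concerned the apicoplast, the relict plastid of the parasite, which the series title names as the target. Its genome encodes ribosomal RNAs, transfer RNAs, ribosomal proteins and a few other proteins. Transcripts of this genome were lower under doxycycline. The mean log2 difference of the 53 features was -0.50 ± 0.59 (SD, n = 12 times), 70.7% of the control level, and it lay below 0 at 10 of 12 times. The two-sided exact sign-flip permutation test over the 12 times gave p = 0.0166, and p = 0.0381 after Benjamini-Hochberg adjustment over 6 lists. Of these lists, 3 are classes within the apicoplast genome and share its features, so the adjustment was not over separate lists. The 95% interval of the mean ran from -0.88 to -0.12. After quantile normalization the mean was -0.47 and p = 0.0615. These values treat the 45 h and 50 h pairs as separate. With both averaged as 1 pair, the mean was -0.51 ± 0.52 (SD, n = 11), below 0 in 10 of 11 pairs, with an exact permutation p = 0.00977. Without the 30 h and 50 h pairs the mean was -0.56 with an exact permutation p = 0.0156, and without the 30 h and 45 h pairs it was -0.41 with p = 0.0645. These last 3 settings were chosen after the data were seen.

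At 20 h and 25 h these transcripts were at their highest in the control. In the control arm the mean of the list went from -1.21 at 10 h to 0.22 at 20 h and 0.11 at 25 h. In the doxycycline arm it was -1.64 at 10 h, -1.07 at 20 h and -0.21 at 25 h. The difference was -0.12 at 0 h, -1.28 at 20 h, -1.08 at 45 h and -1.35 at 55 h. It was above 0 at 40 h, at 0.48, and at 50 h, at 0.40. The values of 45 h and 50 h rest on the doubled control array, and their mean was -0.34. The control means of the list were -1.18 at 45 h and -1.21 at 50 h. Their opposite signs thus came from the doxycycline arrays, with means of -2.27 at 45 h and -0.81 at 50 h. At 20 h, 47 of 49 measured features were below 0, and at 45 h, 52 of 53, but at 40 h only 9 of 48 and at 50 h 9 of 53.

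**Figure D2:**
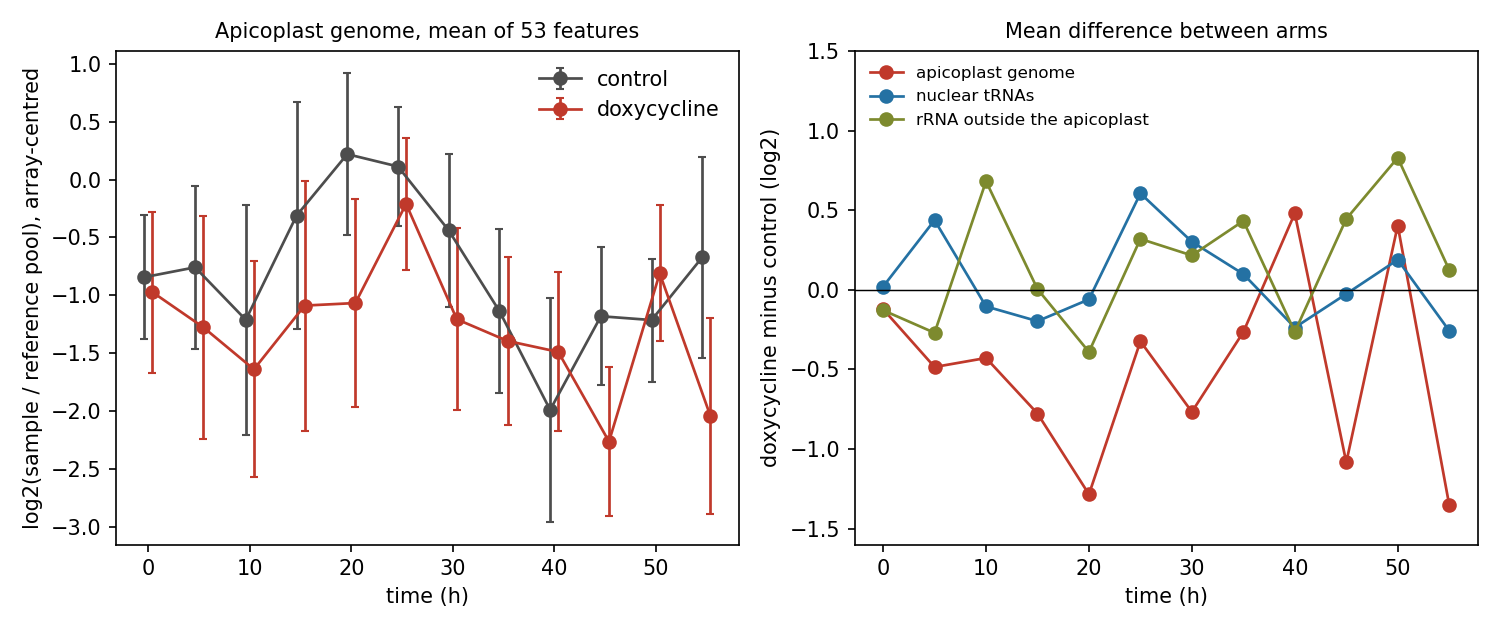
Left, mean log2 ratio of the 53 apicoplast genome features against time in h for each arm, with bars for the SD over features. Right, mean difference of doxycycline minus control (log2) against time for the apicoplast genome, nuclear tRNAs and rRNA outside the apicoplast, where the apicoplast list lies below 0 at 10 of 12 times and reaches -1.28 at 20 h and -1.35 at 55 h.

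In the early period, 0 to 25 h, the list was below 0 at all 6 times, with a mean of -0.57 ± 0.41 (SD, n = 6) and an exact permutation p = 0.0312, the smallest that 6 times can give. This early test was not among those planned for the list, and its p-value was not adjusted over the lists. In the late period, 30 to 55 h, the mean was -0.43 ± 0.77 (SD, n = 6), below 0 at 4 of 6 times, and the exact permutation p was 0.25. The late mean was -0.25 without the 55 h pair, -0.27 after quantile normalization and -0.18 without the 30 h and 45 h pairs, a setting chosen after the data were seen. The late mean minus the early mean was 0.14, and exact permutation of the period labels gave p = 0.69; over all settings it ran from -0.07 to 0.39, with p of at least 0.352. The periods were therefore not shown to differ.

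No apicoplast feature passed on its own in the limma fit over 7549 features. The mean difference over both periods was negative in 52 of 53, against 3694 of 7496 other features. When adjusted over the list alone, 18 of 53 were lower. The features share the same 12 time pairs and correlate at an estimated 0.633, so these counts are not separate evidence from each feature. The list was drawn from probe names when the file was opened, by name and not by value. All 12 other protein-coding features were below 0, and 8 were lower when adjusted over these 12 alone. When adjusted over the 53, only tufA, rpoC, rpoB and ORF78 of the 12 were lower. The elongation factor Tu, tufA, had -0.80 ± 0.18 (SE), and the RNA polymerase subunits rpoC and rpoB had -0.69 ± 0.21 and -0.67 ± 0.19. ORF78 was below 0 at 12 of 12 times, with -0.78 ± 0.16. The others were ORF129, Clp, ORF470, ORF101, ORF91, ORF79, ORF105 and ORF51, from -0.61 to -0.20.

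All 17 apicoplast ribosomal proteins were below 0, with 7 lower over these 17 alone. They ran from rps2, at -0.75 ± 0.25 (SE), and rps7, at -0.69 ± 0.19, to rpl2, at -0.13 ± 0.18, and rpl4, at -0.07 ± 0.17. Of 22 apicoplast tRNAs, 21 were below 0 and 5 were lower over these 22 alone. tRNALeu had the lowest value of the genome, -1.21 ± 0.22 with an adjusted p of 0.12 over all features, and tRNAArg had -1.20 ± 0.30. tRNAPhe, tRNASer, tRNATyr, tRNAGln, tRNAAsn, tRNAAsp, tRNAGly, tRNAArgPrime, tRNATrp, tRNAAla, tRNASer2, tRNAThr, tRNAGly2, tRNAHis, tRNACys, tRNAMet, tRNALys, tRNAPro and tRNAVal lay between -0.86 and -0.01. tRNAIle, at 0.39 ± 0.32, was the one above 0, with 1.57 in the early period and -0.79 in the late period. After quantile normalization tRNAVal and tRNALys also lay above 0. The small subunit rRNA had -0.59 ± 0.17 and the large subunit rRNA -0.22 ± 0.15.

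**Figure D3:**
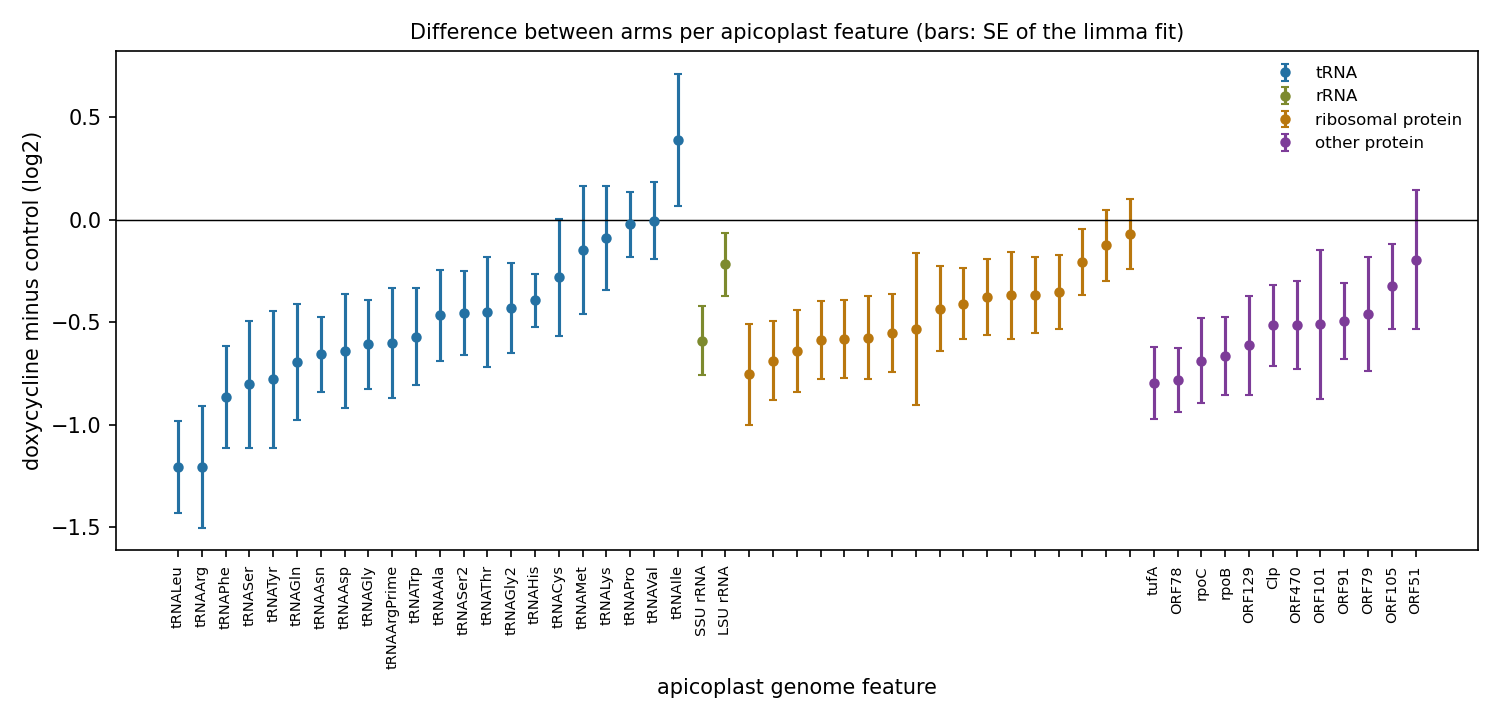
Difference of doxycycline minus control (log2, mean of the early and late periods) for each of the 53 apicoplast genome features, grouped by kind, with bars for the SE of the limma fit and ribosomal proteins drawn without names. In the plot 52 of 53 points lie below 0, with tRNAIle above.

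Set tests were run on the apicoplast genome, its 3 larger classes, nuclear tRNAs and rRNA outside the apicoplast. With the preset correlation, camera gave the apicoplast genome an adjusted p of 2.0e-20 for the mean over all times and 5.2e-07 for the late period. With the estimated correlation of 0.633 between its features, the adjusted p was 0.0886 for the mean and 0.373 for the late period, so neither call was kept. Set tests had been planned only for the mean over all times and the late period. For the early period the adjusted p with the estimated correlation was 0.0476 for the apicoplast genome, 0.0427 for both its other proteins and its tRNAs, and 0.118 for its ribosomal proteins. On the values as deposited these were 0.075, 0.0604 and 0.162, so no early call was kept there. The fry test, which asks whether a list moves one way and does not compare it with other features, gave the apicoplast genome an adjusted p of 0.0464 for the mean, 0.245 for the late period and 0.106 for the early period. Both fry and the estimated correlation used only features measured at all times, 40 of the 53 for the apicoplast genome.

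The list of nuclear tRNAs holds the tRNA features not named for the apicoplast, 5 of them named unmapped and so placed on no chromosome. Their mean difference was 0.06 ± 0.27 (SD, n = 12 times), with 15 of 22 features above 0 and an exact permutation p = 0.436. The rRNA probes outside the apicoplast had a mean of 0.17 ± 0.39 (SD, n = 12) and an exact permutation p = 0.166. In the late period 15 of 17 of these were above 0, with a mean of 0.30 ± 0.37 (SD, n = 6) and an exact permutation p = 0.125. The largest difference of this list, 0.83 at 50 h, rests on the doubled control array. Without the 30 h and 50 h pairs, a setting chosen after the data were seen, the mean was 0.10 (exact permutation p = 0.410). The late mean was then 0.18 (exact permutation p = 0.375). Camera with the preset correlation gave these rRNA probes an adjusted p of 0.00714 for the mean and 0.000182 for the late period. With the estimated correlation the adjusted p was 0.255 and 0.373. The highest late values were chr5.rRNA1ITS1A, at 0.71, and oPFrRNA0007, at 0.65, and the lowest were chr8.rRNA328spseudo, at -0.33, and oPFrRNA0004, at -0.22. Among the nuclear tRNAs the highest late values were chr4tRNAIle1, at 0.72, and chr5tRNAArg1, at 0.61, and the lowest were unmapped1tRNAGly1, at -0.66, and chr6tRNALeu1, at -0.46. The means over all times were 0.11 ± 0.18 (SE) for pfcrt, 0.06 ± 0.13 for HRPII, -0.04 ± 0.17 for HRPIII, 0.20 ± 0.17 for HRP and 0.18 ± 0.13 for MND1, and none of these 5 passed.

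Over all 7549 features, limma called 0 changed at an adjusted p of 0.05 for the mean over all times, 0 for the late period, 0 for the early period and 0 for late minus early. With array weights it called 1207 for the mean and 2355 for the late period, but 0 for each when the 45 h pair, which the weights favoured, was also left out. At an unadjusted p under 0.05 there were 803 features for the mean, 830 for the late period, 415 for the early period and 342 for late minus early, where chance alone gives about 377. The strongest features for the mean over all times, none of which passed, were N134_93_1, at 0.80 ± 0.13 (SE), and B140_1, at 0.67 ± 0.12, among the positive ones. Among the negative ones they were Ks1196_1_1, at -0.96 ± 0.14, J697_3_1, at -0.82 ± 0.13, and the apicoplast tRNALeu was also among the 5 strongest. The others are probe IDs that the files do not pair with gene names. For late minus early the strongest negative feature was the locus tag PFA0730c, at -2.79 ± 0.55 (SE) with an adjusted p of 0.938. Without the 30 h pair, 72 features passed in the late period, 65 lower and 7 higher, of which 0 belonged to the apicoplast genome, and 8 passed for the mean. These counts take the 45 h and 50 h pairs as separate, and with both averaged and 30 h left out 0 passed in the late period and 1 for the mean. Without both the 30 h and 50 h pairs, 18 passed in the late period, 1 for the mean and 4 for late minus early, and without the 30 h and 45 h pairs 0 passed in limma in any of these, with 1084, 1053 and 624 at an unadjusted p under 0.05.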

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

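The tests of a difference between the cultures, of the counts at an unadjusted p, without the 30 h and 45 h pairs, with the 45 h and 50 h pairs averaged, and of the stage comparisons with a time left out were chosen after the results were seen, and the test without the 30 h and 50 h pairs after the data were seen. Probes whose names start with Z were left out of every comparison, yet they carried signal: the median correlation of their profiles between the arms was 0.846, against 0.43 for empty spots.

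The apicoplast genome was lower under doxycycline, by -0.50 on the log2 scale over 12 times (SE 0.171), and against array scaling as the whole cause it still lay -2.10 standard errors from 0 after quantile normalization, although its exact permutation p there was 0.0615. Against a shift of stage as the whole cause, each doxycycline array was set against the control interpolated to its best matching time. The mean was then -0.49 (exact permutation p = 0.00732), and -0.56 to -0.42 with each time left out in turn (p at most 0.0146). The interpolated controls share arrays between pairs, and the 55 h array was set against the control at 3 h. These p-values treat such pairs as separate. Features without an apicoplast name, matched on their control profile, gave a weaker test. The list lay -2.27 standard errors from them over 12 times (exact permutation p = 0.0410). Without 30 h it lay -1.87 standard errors from them (exact permutation p = 0.0820), and the matched features averaged -0.12 in place of -0.04. With each time left out in turn, it lay within 2 standard errors in 5 of 12 settings. The exact permutation p was also over 0.05 without 5 h (0.0664) and without 10 h (0.0625), where the list lay beyond 2 standard errors. Against the 30 h array and the doubled control array as the whole cause, the mean was -0.56 (exact permutation p = 0.0156) without 30 h and 50 h, and -0.49 (p = 0.0195) with 45 h and 50 h averaged and 30 h left out, while without 30 h and 45 h it was -0.41 (SE 0.193, p = 0.0645), a smaller mean over fewer times. A difference between the cultures that predates the treatment cannot be told apart from an effect of doxycycline, because each arm has 1 array at 0 h, where the difference was -0.12, and an effect of doxycycline on apicoplast transcripts stays open as a hypothesis.

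The control arrays of 45 h and 50 h shared 10.5% of their values exactly, against at most 0.567% in any other pair. Their empty spots, which hold no parasite probe, correlated at 0.858, against at most 0.496 in any other pair, a gap of 0.362. That gap argues against parasites merely at the same stage, and is consistent with one hybridisation deposited under both times. Which time the array belongs to stays open.

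Swapping the arms within times says nothing about chance for the 4 counts of changed features, since a real count of 0 is reached by every split: all 100 drawn for the mean (highest other 33), all 100 for late minus early (highest other 4), all 32 for the late period (highest other 427) and all 32 for the early period (highest other 0). The 427 came from swapping the 30 h pair alone. That points to a structure of the samples in which, for those features, the arms at 30 h differ in the opposite direction to the other late times. It does not hold for the apicoplast list, which was at -0.77 at 30 h and at -0.43 in the late mean. At an unadjusted p under 0.05, 12 of 100 splits reached the 803 features of the mean (highest other 1587) and 11 of 32 reached the 830 of the late period (highest other 1849), so chance is not excluded for these counts.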

How the results depend on the processing

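Leaving out the 30 h and 50 h or the 30 h and 45 h pairs, averaging the 45 h and 50 h pairs, and leaving out a pair under array weights or with the interpolated control were chosen after the data were seen, and all other alternatives were planned. The apicoplast mean over all times stayed below 0 in every alternative, from -0.61 to -0.41, with exact permutation p from 0.00195 to 0.0645; it missed the threshold after quantile normalization (-0.47) and without the 30 h and 45 h pairs (-0.41, 10 times), where the cause was not tested. Leaving out 1 time pair gave -0.59 to -0.42 for all times, -0.61 to -0.25 for the late period and -0.04 to 0.32 for late minus early; with 5 late pairs the late test cannot reach the threshold. After quantile normalization and without the 30 h and 45 h pairs the late mean was -0.27 and -0.18, and late minus early 0.39 in both. The counts of changed features, each 0 as reported, were higher under some settings. For the mean over all times they were 9 as deposited, 1 without the 30 h and 50 h pairs, 1 with the 45 h and 50 h pairs averaged and 30 h left out, 1207 with array weights (1191 without the 30 h pair, 0 without the 45 h pair) and 16 with the control interpolated to the best matching time, and 0 to 8 with 1 pair left out. For the late period they were 18 without the 30 h and 50 h pairs, 4 with the late period from 35 h, 2355 with array weights (2276 without the 30 h pair, 0 without the 45 h pair), 2 with the interpolated control, and 0 to 72 with 1 pair left out, the 72 without 30 h. For late minus early they were 4 without the 30 h and 50 h pairs and 5 with array weights (6 without the 30 h pair, 0 without the 45 h pair), and for the early period 1 with the interpolated control. The weights gave the 45 h pair 8.03 and every other pair at most 1.74, and the counts under weights depended on that pair; the cause was not tested for the others. For the gene lists, the estimated correlation gave adjusted p = 0.0886 (apicoplast, mean), 0.373 (apicoplast, late), 0.255 (rRNA, mean) and 0.373 (rRNA, late), and fry gave 0.245 (apicoplast, late), 0.235 (rRNA, mean) and 0.245 (rRNA, late); the estimated correlation of 0.633 between apicoplast features widens the first of these tests, and the cause was not tested for fry. tRNALeu passed over all features as deposited (-1.31) and with the interpolated control (-1.38). Over the alternatives, the median absolute offset of the matching times was 1 to 1.5 h, and the median profile correlation was 0.734 to 0.846.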

Other observations

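The tests in this part were chosen after the results were seen. At 55 h both arms resembled the start of the series. Among control arrays of 0 to 25 h, the control array of 55 h matched best at 8 h, with a correlation of 0.751, and the doxycycline array of 55 h matched best at 3 h, with 0.815. The gap of 5 h was 4 h by Spearman correlation and 5 h over the more variable features. Treated parasites may thus have been behind the control on entering the second cycle, a hypothesis that rests on 1 array per arm.

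A delay of the apicoplast profile was also tested. The mean apicoplast profile under doxycycline correlated with the control profile 5 h earlier at r = 0.681 (permutation p = 0.0207, adjusted p = 0.0622 over 3 relations; Spearman's rho = 0.564, permutation p = 0.076), with that of the same time at r = 0.485 (permutation p = 0.107; rho = 0.406, permutation p = 0.192) and with that 5 h later at r = 0.373 (permutation p = 0.257; rho = 0.491, permutation p = 0.13). Without the 2 times farthest from the median of the control profile, r was 0.185 with the profile 5 h earlier, 0.564 with that of the same time and 0.421 with that 5 h later. The order that a delay predicts was then reversed, so the relation rests on those times and no delay is shown. Neighbouring times are not independent, which makes these p-values too small.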
